A study of Mus musculus with 6 samples.

How the data were processed

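RNA from the intestine of 3 wild type and 3 FcεRIα knockout BALB/c mice was sequenced, 1 library per mouse. Groups and replicate numbers came from the sample titles, and the 3 mice per group from the design text of the series. The tissue label reads intestine and the title of the series speaks of epithelial cells. Total RNA was extracted with TRIzol, treated with DNase I and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. TopHat2 version 2.0.0, an aligner, and the mouse build mm10 are named per the submitters' processing notes, which were available here as names only. The counting program, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart with certainty. The deposited tables hold an estimated count per gene, since 12.4% to 14.8% of features had a fractional value, and the same 56362 features stand in each. Of these, 948 carried an identifier from transcript assembly in place of an Ensembl one, and took 0.436% to 0.978% of the counts. Gene names came from the deposited tables. Coordinates came from GENCODE vM21 (GRCm38, the assembly that mm10 names), which held 52133 of the identifiers and not the other 4229.

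Counts were rounded to whole numbers. No 2 libraries of a group were copies of each other, since the chi-square per degree of freedom between their counts ran from 33.8 to 247. Depth was 19488920, 21591133 and 19031833 counts in wild type and 21981206, 22057616 and 23092382 in knockout libraries. Intervals at 95% on ratios of counts were exact binomial, and a level of 0 was set against 3 counts. Both cover counting error only.

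The main test was edgeR 4.0.16's quasi-likelihood test (glmQLFit and glmQLFTest, in R 4.3.3) with TMM normalization and no block, on the genes kept by filterByExpr (minimum count 10), which left 16732 and dropped 39630. The threshold was a Benjamini-Hochberg adjusted p under 0.05. CPM values use TMM-scaled library sizes, and the ± values are SDs over 3 mice. SEs of fold changes are the fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.395. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on lists with 5 or more tested members, with an estimated correlation and fry beside it. Some genes belong to more than 1 list, so results of related lists are not independent. Fcer1a was kept past the filter only for its own value. DESeq2 1.42.0 and limma-voom were alternatives, as were RLE and upper quartile factors, no scaling factors, other filters on low counts, a replicate block, and leaving out each library. A fit with the mean level of the epithelial markers as a covariate, the newer version of edgeR's method and KEGG groups in place of the lists were added after the data were seen. The design, the lists, the other alternatives and the rule for named genes were fixed before the data were examined.

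The rule named Fcer1a and, among genes past the threshold whose groups did not overlap, the 10 of largest fold change each way. Where fewer passed, the places went to the genes of smallest p, named as not passing. Genes under 1 CPM in both groups, genes with no proper name, pseudogenes and immunoglobulin or T cell receptor segments were left out. Up to 4 members of smallest p were named from lists that passed camera or held a called gene, and the rest were given as counts. Other genes in the text (Cpa3, Ms4a2, Per2, Cyp2c55, Fam20b, Il12a, Tgtp2, Dnah8 and those of the closing section) were chosen after their values were seen.

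The steps were tested on simulated counts for the 16732 genes of this comparison, drawn with their means, library sizes and spread, with 200 genes changed. edgeR recovered 10% of 2-fold, 56% of 4-fold, 86% of 8-fold and 94% of 16-fold changes, and called 0.0302% of the 16532 unchanged genes. DESeq2 recovered 26%, 80%, 94% and 100%, and called 0.405% of the unchanged genes, and limma-voom 8%, 58%, 82% and 94%, with 0.0363%. Camera called 0 of 55 lists when genes varied independently with no change, and 1, the raised one, when the interferon gamma list was raised. Genes of a list do not vary independently in the real libraries, which that simulation leaves out.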

Results

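RNA was sequenced from the intestine of BALB/c mice, per the labels, in 3 wild type mice and 3 mice lacking FcεRIα, the alpha chain of the high-affinity receptor for IgE. Each library came from 1 mouse, per the design text of the series. The tissue label reads intestine, while the title of the series speaks of epithelial cells, so whether stroma was meant to be in the samples is not known. Every sample title holds the letters DSS, which the labels do not expand, and no sample without those letters was used here. The tables held estimated read counts for 56362 features. Totals ran from 19031833 to 23092382 counts per library, so that a count of 0 in 1 library allowed a level of up to 0.124 to 0.187 CPM (counts scaled to a common TMM-scaled library total; the level of 3 counts, counting error only). The design implies 1 comparison, the gut of knockout mice against that of wild type mice, and asks how loss of the receptor chain changed gene expression there.

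Fcer1a, the targeted gene (ENSMUSG00000005339, chromosome 1, 173221284 to 173227214, minus strand, GENCODE vM21 on GRCm38), was almost without reads in knockout gut. The knockout libraries held 1, 0 and 0 counts and the wild type libraries 0, 10 and 18. The group totals of 1 and 28 counts gave a ratio of 0.0320, with a 95% interval of 0.000782 to 0.193 from counting error only. Wild type library 1 also stood at 0 counts. It held few reads of other mast cell genes as well, with 7 counts of Cpa3, a mast cell protease, against 37 and 84 in wild type libraries 2 and 3, and 9, 15 and 23 in the knockout libraries. Ms4a2, the beta chain of the same receptor, had 0, 12 and 13 counts in wild type and 1, 4 and 7 in knockout libraries. An exact permutation test of the Fcer1a levels gave p = 0.40, two-sided, where 3 against 3 cannot go below 0.10. Counts this low failed the filter of the gene-wide test, and the label of wild type library 1 could not be checked by this gene. On 3 genes near absent in 1 group it went with wild type (Glo1-ps, 229 counts against 0 in each knockout library, Gm10503, 143 against 0, 0 and 1, and Tgtp1, 1 against 297 to 1484), but these were picked by the group labels after the values were seen and are no independent check.

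The genes with higher levels in knockout gut are named by smallest p, and none passed the test. Tgtp1, an interferon-inducible GTPase (chromosome 11, 48985327 to 48994172), had 1, 0 and 0 counts in wild type and 297, 1484 and 582 in knockout libraries, a ratio of 2116 with a 95% interval of 379 to 83609 from counting error only. Iigp1, another GTPase of this class, was at 29.8 ± 12.8 CPM (SD, n = 3) in wild type and 232 ± 103 CPM in knockout gut, a log2 fold change of 2.96 (SE 0.49). Irgm2 and Gvin2 of the same class differed by 2.16 (SE 0.38) and 2.17 (SE 0.36). The chemokine Cxcl10 differed by 1.65 (SE 0.29) and Znfx1, an RNA helicase of antiviral defence, by 0.90 (SE 0.16). The others of the 10 were Apob, the main protein of chylomicrons, at 3.08 (SE 0.51), Nr1d1, a transcriptional repressor of the circadian clock, at 1.56 (SE 0.26), Hnf4g, a nuclear receptor of enterocytes, at 1.45 (SE 0.25), and Cracd, a regulator of actin capping, at 0.76 (SE 0.13).

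Among the genes with lower levels in knockout gut, Cry1, a repressor of the circadian clock (chromosome 10, 85131700 to 85185064), was at 40.0 ± 6.34 CPM in wild type and 15.5 ± 1.17 CPM in knockout gut, a log2 fold change of -1.37 (SE 0.18, n = 3 per group). S100a9, a subunit of calprotectin from neutrophils and inflamed epithelium, differed by -1.92 (SE 0.26). The detoxifying enzymes Glo1 (chromosome 17, 30584936 to 30626871), Gsta1 and Gsta2 differed by -1.34 (SE 0.27), -1.65 (SE 0.35) and -2.71 (SE 0.54). The metal-binding protein gene Mt2 differed by -1.13 (SE 0.25), the collagen prolyl hydroxylase gene P4ha1 by -0.82 (SE 0.16) and Ahsa2, an activator of the chaperone Hsp90, by -0.85 (SE 0.19). Pea15a, a regulator of ERK signalling whose gene lies close to Fcer1a, differed by -1.06 (SE 0.23).

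None of these genes passed the test. The rule took 20 genes, of which 1 was not used here. Of 16732 genes tested by edgeR's quasi-likelihood method, 0 passed at an adjusted p under 0.05, with 0 higher and 0 lower. The smallest adjusted p was 0.136, and 1145 genes had an unadjusted p under 0.05 against 837 if p were uniform. The 9 other splits of the 6 libraries, which mix the genotypes, gave 65 to 3144 such genes, so 837 is not what chance gives in these samples. DESeq2 called 127 genes, 86 higher and 41 lower, among them 19 of the 20, and limma-voom called 2. In the simulated counts, however, the share of false calls among DESeq2's calls lay above the threshold of 0.05. Among all tested genes, 2175, or 13.0%, had all 3 libraries of 1 group above all 3 of the other, where chance gives 10% as a mean over splits. A single split can lie far from that mean when genes vary together, so 13.0% alone shows no excess by genotype. The named genes parted the groups in this way as well, which follows from how they were picked and is no evidence of its own. Gsta1 and Gsta2, and Tgtp1 and its neighbour Tgtp2, are near-identical copies between which the counting could divide reads. Glo1 shares sequence with its pseudogene Glo1-ps and overlaps Dnah8 on the other strand, so its value is uncertain in the same way.

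Genes of the type 1 and interferon gamma response stood out as a group. Of its 20 tested members, 19 were higher in knockout gut, with a median log2 fold change of 1.67, and in 11 of them all knockout libraries lay above all wild type libraries. Ifng itself, the cytokine gene, had 0, 2 and 1 counts in wild type and 14, 12 and 11 in knockout libraries, a ratio of 11 with a 95% interval of 3.50 to 56.0 from counting error only. Besides Cxcl10, the members of smallest p were the guanylate-binding protein genes Gbp4, at 2.66 (SE 0.53), and Gbp5, at 1.35 (SE 0.30). Counted with p adjusted over the list alone, 14 of the 20 genes passed edgeR's test, and 0 with p adjusted over all genes. The list passed limma's camera test with a preset correlation (adjusted p = 8.6e-12), but not with an estimated one (adjusted p = 0.860 with an estimated correlation). Its unadjusted p by camera with an estimated correlation was 0.0584, and other lists shared the adjusted value of 0.860. At the preset correlation camera also called the list on some splits that mix the genotypes, so a small p there is not particular to genotype. The fry test found no shift 1 way (adjusted p = 0.530), and its test of change in either direction gave an adjusted p of 0.0408. By library, the mean of the list relative to the 6 libraries was -0.31, -1.21 and -0.63 in wild type and 1.03, 1.09 and 0.03 in knockout gut.

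**Figure D1:**
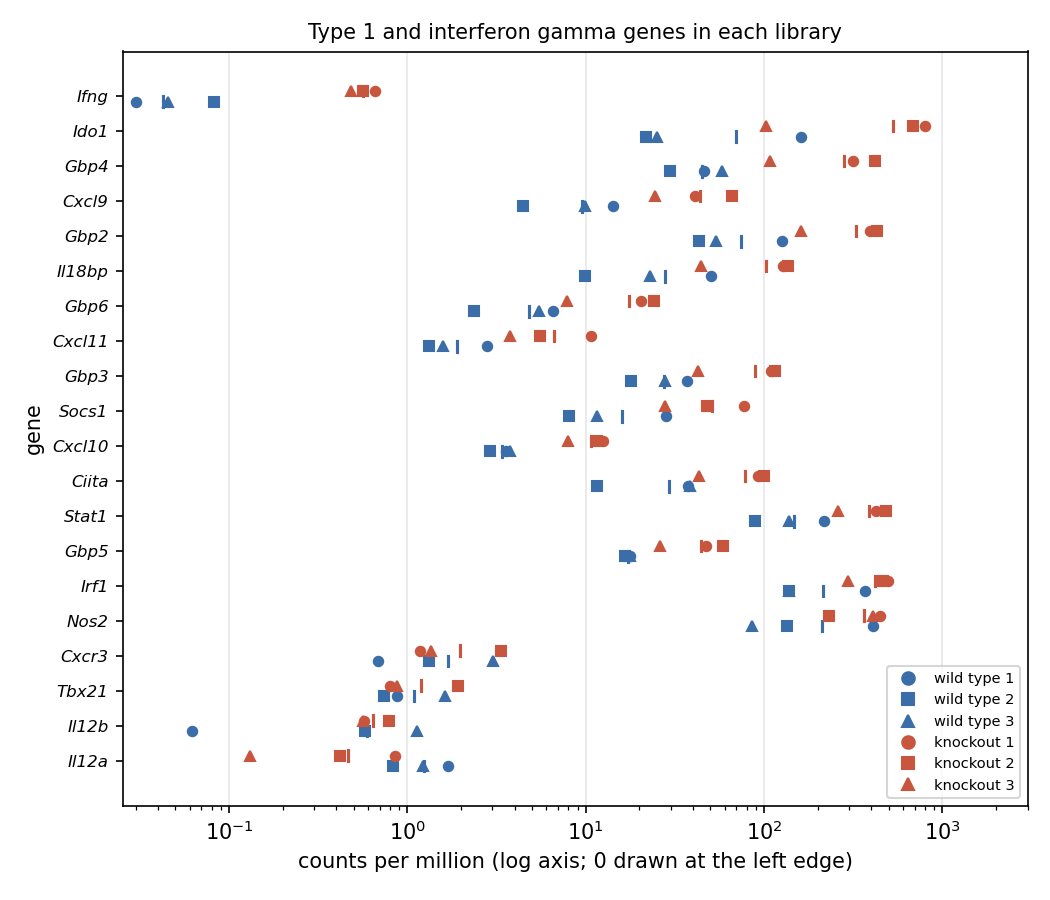
Level of each tested member of the type 1 and interferon gamma list in CPM on a log axis, with 1 point per library and a short bar at each group mean, ordered by fold change. All members but Il12a have the higher fitted level in knockout (19 of 20), and in 11 of 20 the knockout points all lie above the wild type points.

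Neighbouring interferon and antigen presentation lists also lay higher in knockout gut on average, although wild type library 1 lay above at least 1 knockout library in the mean of each list. Its means were 0.48 for type I interferon, 0.18 for class I, 0.65 for class II and 0.24 for cell death genes, against 0.29, 0.01, -0.28 and 0.01 in knockout library 3. Of 20 genes of the type I interferon response, 19 were higher (median 0.76), with Usp18 at 1.94 (SE 0.46), Ifit3 at 1.28 (SE 0.39) and Ifi44 at 1.15 (SE 0.36). All 13 tested genes of MHC class I and antigen processing were higher (median 1.03), among them the peptide transporter gene Tap1 at 1.62 (SE 0.50) and Nlrc5, the activator of MHC class I genes, at 1.16 (SE 0.42). Of 9 MHC class II genes, 8 were higher (median 0.64), led by their activator Ciita at 1.43 (SE 0.52), which is also in the interferon gamma list. Of 21 genes of apoptosis, pyroptosis and necroptosis, 14 were higher (median 0.51), with Fas at 1.11 (SE 0.37) and Bak1 at 0.51 (SE 0.16). In these 4 lists, 0 genes passed edgeR's test with p adjusted over all genes and 0 adjusted over the list alone, and 18 had an unadjusted p under 0.05. The 4 lists passed camera at the preset correlation (adjusted p = 4.7e-09, 3.3e-08, 0.00951 and 0.00679), and lost the call with an estimated one (adjusted p = 0.860, 0.860, 0.900 and 0.900 with an estimated correlation). Without wild type library 2 the class II list fell short of the threshold (median 0.22, camera adjusted p = 0.348), as did the apoptosis list without wild type library 3 (0.0824). With the epithelial markers as a covariate, a fit chosen after the data were seen, the class II and apoptosis lists lost the call (medians 0.25 and 0.37, adjusted p = 0.525 and 0.296). The type I median was then 0.50. Without wild type library 1 the medians of the type I, class II and apoptosis lists were 1.42, 1.29 and 0.97, and without knockout library 2 that of the class II list was 0.42.

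Genes of acute inflammation and of neutrophils lay lower in knockout gut on average, but the mean of each list in wild type library 1 lay within or below the knockout range. Single genes parted the groups, 5 of the proinflammatory list, S100a9 and S100a8 of the neutrophil list and 0 of the other 2. Of 20 proinflammatory cytokine and chemokine genes, 18 were lower (median -1.42), with Saa3, an acute-phase protein gene, at -2.33 (SE 0.59), the neutrophil chemokine Cxcl2 at -2.77 (SE 0.74), Ccl7 at -1.03 (SE 0.30) and Il1a at -1.54 (SE 0.46). Of 10 neutrophil markers, 9 were lower (median -1.21), with S100a8 at -1.61 (SE 0.52). All 9 tested type 17 cytokine genes were lower (median -0.94), led by Cxcl1 at -2.19 (SE 0.70), which is also in the proinflammatory list, and Lcn2 at -2.03 (SE 0.74). Among 15 matrix protease genes 14 were lower (median -1.17), with Mmp10 at -2.63 (SE 1.17) and Mmp13 at -2.23 (SE 0.96). Mmp10 was at 8.36, 206 and 105 CPM in wild type libraries 1, 2 and 3, and at 10.6, 4.90 and 36.0 CPM in knockout libraries, so that wild type library 1 lay within the knockout range. By library the proinflammatory means were -0.63, 1.28 and 0.95 in wild type and -0.50, -0.98 and -0.13 in knockout gut. The neutrophil means were -0.22, 0.74 and 0.57 against -0.88, 0.09 and -0.30. The protease means were -1.26, 1.45 and 1.12 against -0.92, -0.51 and 0.12. Fibroblast and matrix genes ran alike in wild type, at -1.66, 1.08 and 1.23, and were at -1.15, 0.43 and 0.08 in knockout gut. With the epithelial covariate the medians were -0.29 for proinflammatory genes, -0.02 for neutrophil markers, -0.51 for type 17 genes and 0.022 for proteases, and all but the proinflammatory list lost the call (camera adjusted p = 0.0292, 0.201, 0.162 and 0.565). The adjusted p by camera at the preset correlation was 6.9e-06, 0.00951, 0.0302 and 0.0155 for these 4 lists, and 0.860, 0.860, 0.860 and 0.900 with an estimated correlation. With p adjusted over the list alone, 1 neutrophil marker passed edgeR's test, S100a9, and 0 genes of the other 3 lists, and 0 with p adjusted over all genes. The type 17 list fell short of the threshold without wild type library 1 or 3 or knockout library 2 or 3 (camera adjusted p = 0.0547, 0.270, 0.240 and 0.10), and with upper quartile factors (0.0622). Its median was -1.47 without knockout library 1 and -1.69 by limma-voom. The matrix protease list fell short without wild type library 2 or 3 or knockout library 1 (0.348, 0.224 and 0.105), and the neutrophil median was -0.72 and -0.77 without wild type library 2 and 3.

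Markers of dividing cells, vessels and squamous epithelium were lower on average as well, with the libraries of the groups overlapping in each list. All 20 proliferation genes were lower (median -0.40), with Mki67 at -0.55 (SE 0.30) and Ccnb1 at -0.74 (SE 0.37). None of the 20 parted the groups, 0 had an unadjusted p under 0.05, and their means by library were -0.21, 0.64 and 0.25 in wild type and -0.16, -0.91 and 0.38 in knockout gut. Of 15 endothelial markers 13 were lower (median -0.80), led by the adhesion molecule gene Selp at -2.38 (SE 0.73), and endothelial means by library were -0.88, 0.58 and 1.27 in wild type and -1.06, 0.50 and -0.42 in knockout gut. All 6 tested markers of stratified squamous epithelium, a lining that intestine lacks above the anal canal, were lower (median -1.92), with Krt13 at -2.23 (SE 0.53) and Krt6a at -2.81 (SE 1.16). The mean of the squamous list was 0.06 in wild type library 1 and 0.06 in knockout library 3. Levels were low, with Krt13 at 9.48, 19.9 and 13.2 CPM in wild type and 3.40, 1.21 and 4.40 CPM in knockout libraries. Krt13 passed edgeR's test with p adjusted over the list alone, 1 of the 6, while 0 proliferation genes and 0 endothelial markers did, and 0 of the 3 lists with p adjusted over all genes. By camera at the preset correlation the adjusted p was 0.000332, 0.0176 and 0.00470, and 0.900, 0.900 and 0.860 with an estimated correlation. Leaving out 1 library ended the call of the proliferation list (knockout 2, camera adjusted p = 0.181), the squamous list (wild type 1, 0.0709) and the endothelial list (wild type 3, 0.639, knockout 1, 0.201, and knockout 3, 0.0823). The proliferation median was -0.61, -0.14, -0.17 and -0.76 without wild type 1, wild type 2, knockout 2 and knockout 3. The squamous median was -0.81 without wild type 2, and the endothelial one -1.30, -0.28 and -1.38 without wild type 1, wild type 3 and knockout 2. With the epithelial covariate the medians were -0.12 for proliferation, 0.30 for endothelium and -1.16 for squamous markers (camera adjusted p = 0.124, 0.883 and 0.0252).

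Epithelial genes lay slightly higher in knockout gut on average. Of 15 epithelial cell markers 14 were higher (median 0.31), with Hnf4a at 0.38 (SE 0.23) and Cdx2 at 0.39 (SE 0.28). By library their means were 0.37, -0.34 and -0.51 in wild type and 0.29, 0.11 and 0.08 in knockout gut, with wild type library 1 the highest of the 6, as it was for the goblet list (0.72). Goblet cell and mucus genes (14 of 18 higher, median 0.25), junction genes (15 of 21 higher, median 0.30) and small intestinal enterocyte markers (7 of 12 higher, median 0.40) went the same way, with Muc2 at 0.55 (SE 0.47), Ocln at 0.31 (SE 0.13) and the glucose transporter gene Slc5a1 at 0.88 (SE 0.29). The junction means by library were -0.06, -0.05 and -0.09 in wild type and 0.08, -0.04 and 0.16 in knockout gut. The enterocyte means were -0.02, -0.42 and -0.21 against 0.39, 0.17 and 0.08. In the means of the junction and enterocyte lists the groups thus did not overlap, unlike in the epithelial and goblet lists. The enterocyte list holds Apob, which alone among these 4 lists passed edgeR's test with p adjusted over the list alone, and 0 genes of them passed with p adjusted over all genes. The epithelial, goblet, junction and enterocyte lists passed camera at the preset correlation (adjusted p = 0.0111, 0.0215, 0.0140 and 0.0499), and lost the call with an estimated one (adjusted p = 0.900, 0.900, 0.860 and 0.860 with an estimated correlation). Calls ended without 1 library for the epithelial list (wild type 2 and 3 and knockout 1, camera adjusted p = 0.0510, 0.279 and 0.0768), the goblet list (the same libraries, 0.647, 0.110 and 0.107), the junction list (wild type 3 and knockout 1, 0.106 and 0.0543) and the enterocyte list (wild type 2 and 3 and knockout 1 and 2, 0.370, 0.134, 0.0768 and 0.0553). Medians moved both ways. The epithelial one was 0.55, 0.15 and 0.17 without wild type 1, wild type 3 and knockout 1. The goblet median was 0.94, -0.00012, 0.15 and 0.12 without wild type 1, 2 and 3 and knockout 1. The junction median was 0.16 without wild type 3, and the enterocyte one 0.23 and 0.10 without wild type 2 and knockout 2. With the epithelial covariate all 4 lists lost the call, with medians of 0.06, -0.0040, 0.14 and 0.36 (camera adjusted p = 0.892, 0.565, 0.201 and 0.679). With no filter on low counts the enterocyte median was -0.088, and with a filter at 1 CPM in 3 libraries its call was lost (0.0571). The goblet median was 0.42 by limma-voom.

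Nuclear genes of oxidative phosphorylation (18 of 21 higher, median 0.33) and of cholesterol synthesis (15 of 16 higher, median 0.28) were higher in knockout gut on average, with Sdha at 0.55 (SE 0.16) in the former list. Wild type library 1 had the highest mean of the 6 for oxidative phosphorylation (0.40, against 0.27, 0.17 and 0.10 in knockout libraries), and for cholesterol synthesis knockout library 2 (-0.17) lay below it (0.08). Lower were endoplasmic reticulum stress genes (14 of 16 lower, median -0.24), antioxidant genes (11 of 14 lower, median -0.20) and genes of proximal intestine position (6 of 8 lower, median -0.49), with Hspa5 at -0.40 (SE 0.21), Gclm at -0.64 (SE 0.23) and Cyp2c65 at -1.64 (SE 0.40). The reticulum stress means by library were 0.26, 0.05 and 0.04 in wild type and -0.15, -0.18 and -0.02 in knockout gut. The proximal means were 0.280, 0.148 and 0.034 against -0.262, 0.030 and -0.229. The groups did not overlap in the means of these lists, narrowly so for the proximal one, and overlapped in that of the antioxidant list. Cyp2c65, a cytochrome P450 gene, passed edgeR's test with p adjusted over the list alone, and 0 other genes of these 5 lists did, with 0 adjusted over all genes. These 5 lists passed camera at the preset correlation (adjusted p = 7.4e-05, 0.00269, 0.0215, 0.0426 and 0.0499), and none with an estimated one (adjusted p = 0.860 to 0.900 with an estimated correlation). With the epithelial covariate the medians of oxidative phosphorylation and cholesterol genes were 0.04 and 0.13 and neither passed (camera adjusted p = 0.805 and 0.336). The antioxidant and proximal lists lost the call as well (0.0559 and 0.0762). The proximal list also lost it with RLE, upper quartile or no factors (0.0568, 0.0632 and 0.0714), with DESeq2 (0.0522) and with a filter at 1 CPM in 3 libraries (0.375, median -0.03). Calls ended without 1 library for the cholesterol list (knockout 1, camera adjusted p = 0.106), the reticulum stress list (wild type 1 and knockout 2, 0.400 and 0.0553), the antioxidant list (wild type 1 and 2 and knockout 2, 0.282, 0.0725 and 0.181) and the proximal list (wild type 1 and 2 and knockout 1 and 3, 0.222, 0.0699, 0.0877 and 0.157). The cholesterol median was 0.12 without knockout 1, the reticulum stress median -0.11 without wild type 1. The oxidative phosphorylation median was 0.58, 0.11, 0.19 and 0.20 without wild type 1, 2 and 3 and knockout 1. The antioxidant median was -0.36 and -0.38 without wild type 3 and knockout 3, and the proximal one -0.29 and -0.86 without wild type 2 and knockout 2.

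**Figure D2:**
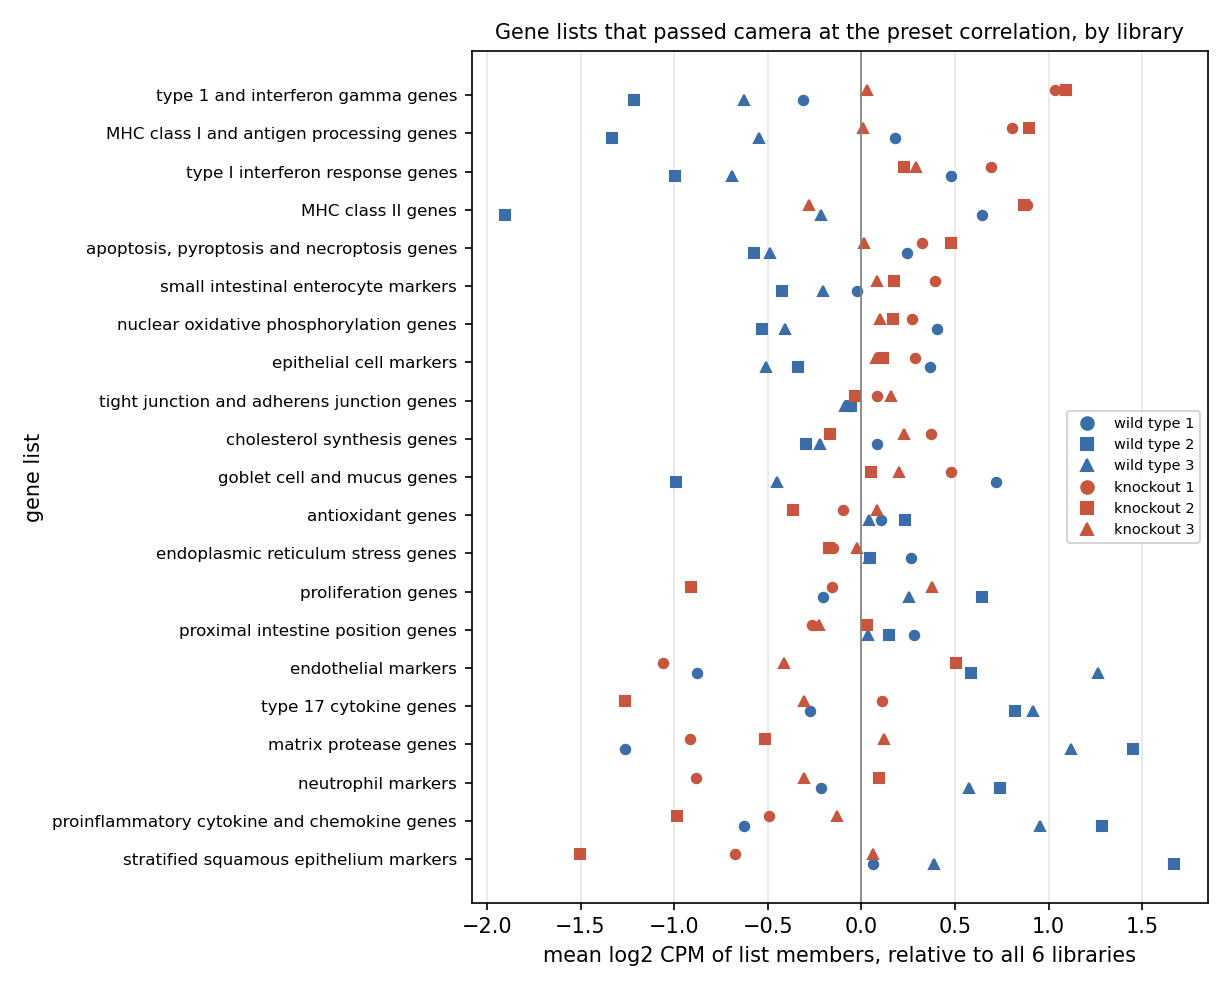
Mean log2 CPM of the tested members of each of the 21 lists that passed camera at the preset correlation, relative to the mean of the 6 libraries, with 1 point per library and the lists ordered by median fold change. For the type 1 and interferon gamma list the knockout points (0.03 to 1.09) lie above the wild type points (-1.21 to -0.31), while for the epithelial cell list wild type library 1, at 0.37, is the highest point. The groups also do not overlap for the junction, enterocyte, reticulum stress and proximal lists.

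In all, 21 of the 55 lists with enough tested members passed camera at the preset correlation, 11 higher and 10 lower, and 0 passed with an estimated correlation or with fry. With change in either direction counted, 4 lists passed fry: the interferon gamma list, the small intestinal enterocyte markers and the proximal position genes (adjusted p = 0.0408 for each) and the circadian clock genes (adjusted p = 0.00264). The clock list had no shift 1 way (median -0.06, 6 higher and 7 lower), and 3 of its 13 genes passed edgeR's test with p adjusted over the list alone: Cry1, Nr1d1 and Per2, which was named after its values were seen, at -0.88 (SE 0.20). With p adjusted over all genes 0 of the 13 passed.

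The libraries did not part by genotype. Component 1 of the 500 most variable genes held 51.5% of the variance and set wild type library 1, at a score of -39.9, and knockout library 1, at -24.1, against wild type libraries 2 and 3, at 37.9 and 33.7. Knockout libraries 2 and 3 lay between, at -9.43 and 1.88. Wild type library 1 correlated with the other wild type libraries at 0.888 and 0.894 across genes, and with knockout library 1 at 0.962. Mitochondrially encoded genes took 10.3% of its counts, against 2.54% to 3.64% in the other 5 libraries, and its 10 most abundant genes 15.8%, against 6.02% to 8.36%. Markers of fibroblasts, endothelium, and enteric neurons and glia were low in it and high in wild type libraries 2 and 3. Their mean log2 CPM, relative to the 6 libraries, was -1.66, 1.08 and 1.23 in wild type libraries 1, 2 and 3 for the fibroblast list, and -1.73, 1.96 and 0.55 for the neuron and glia list. Knockout libraries 1, 2 and 3 were at -1.15, 0.43 and 0.08 for fibroblasts, and at 0.36, -1.17 and 0.03 for neurons and glia. Low values were thus not particular to wild type library 1. The library code of wild type library 3 is of another series than the other 5; a batch by that code would hold 1 library, so no value within it can be given.

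**Figure D3:**
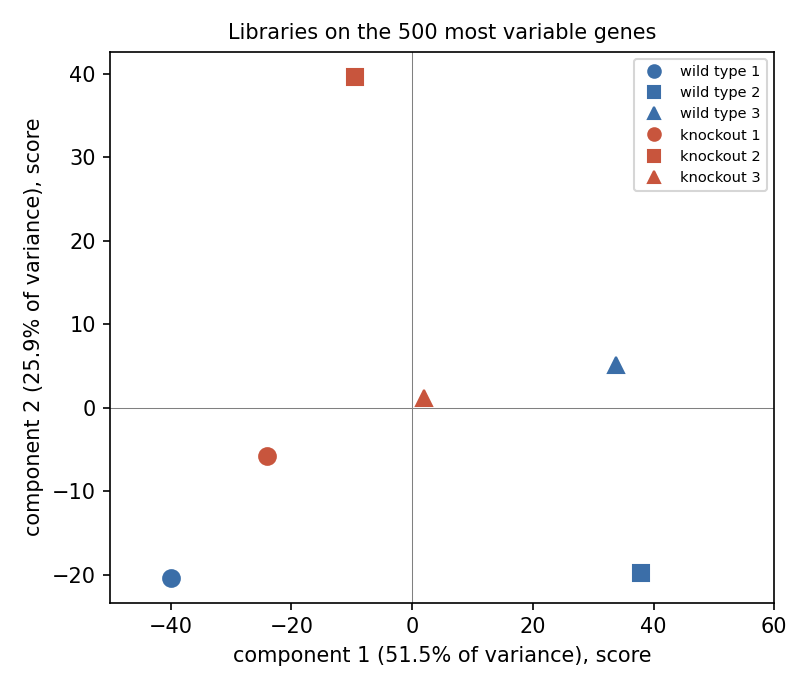
Scores of the 6 libraries on the first components of log2 CPM over the 500 most variable genes, wild type in blue and knockout in red, 1 point per mouse. Component 1 holds 51.5% and component 2 holds 25.9% of the variance, and wild type library 1, at -39.9, lies far from wild type libraries 2 and 3, at 37.9 and 33.7.

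Mast cells carry FcεRI, and their markers were lower in 9 of 10 tested genes (median -0.66), short of the threshold (camera adjusted p = 0.0653, and 0.900 with an estimated correlation). Their means by library were -0.76, 0.61 and 1.03 in wild type and -0.56, -0.48 and 0.16 in knockout gut, with 0 genes passing adjusted over the list alone. The genes of the receptor and its signalling had a median of -0.03 over 13 tested members (camera adjusted p = 0.930), and other Fc receptor genes 0.28 over 9 (adjusted p = 0.399). The lists of basophil, eosinophil, pancreatic acinar and skeletal muscle markers had 1, 2, 3 and 3 tested members and were not tested.

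The remaining lists did not pass camera, and 0 of their genes passed edgeR's test with p adjusted over all genes. Immune cell medians were -0.45 for T cells, -0.23 for regulatory T cells, 0.14 for cytotoxic and NK cells, -0.50 for B cells, -0.54 for plasma cells and immunoglobulins, 0.30 for monocytes and macrophages, 0.58 for dendritic cells, -0.01 for type 2 cytokine genes and 0.10 for complement genes. All 14 T cell genes were lower, but 0 had an unadjusted p under 0.05 and 0 parted the groups, and wild type library 3 alone had a high mean (-0.08, -0.72 and 1.25 in wild type and -0.09, 0.32 and -0.67 in knockout gut). Medians of stromal and other tissues were -0.74 for fibroblasts and matrix, -1.04 for enteric neurons and glia, -0.08 for smooth muscle, -0.09 for adipocytes, -0.35 for liver and -0.99 for haemoglobin genes. Epithelial subtypes had medians of 0.12 for colonocytes, -0.11 for stem cells, -0.21 for regenerating epithelium, -0.32 for Paneth cells, -0.18 for tuft cells, 0.04 for enteroendocrine cells and 0.11 for Hox genes of colon position. For processes the medians were -0.17 for antimicrobial genes, -0.07 for immediate early and heat shock genes, -0.54 for the Wnt pathway, -0.09 for arachidonic acid and leukotrienes, -0.05 for glycolysis and hypoxia, 0.22 for fatty acid oxidation and -0.71 for mitochondrially encoded genes. Wild type library 1 alone had a high mean of the last list (1.51, -0.24 and -0.74 in wild type and -0.01, -0.43 and -0.09 in knockout gut). The list of bile acid and xenobiotic metabolism had a median of -0.12, and 3 of its 16 genes passed with p adjusted over the list alone, which were Gsta1, Cyp2c65 and Cyp2c55, at -2.26 (SE 0.56), named after its values were seen. Among the antimicrobial genes 1 passed with p adjusted over the list alone, S100a9, and in the other lists of these tissues and processes 0 did. The mean went the other way from the median for smooth muscle (0.13 in knockout and -0.13 in wild type, with camera also upward), Paneth cells, enteroendocrine cells and the clock genes.

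A knockout crossed into BALB/c can keep flanking DNA of another strain around the target, so the genes near Fcer1a were counted. Within 20 Mb on each side of it, 0 of 301 tested genes passed edgeR's test, as did 0 of 15865 elsewhere, so that count decides nothing. At an unadjusted p under 0.01, 2 of the 301 (0.664%) and 213 of the 15865 (1.34%) were below, a difference within counting error (Fisher's exact test, two-sided, p = 0.446). The pair were Pea15a, at 172196728 to 172206804 on chromosome 1, and Fam20b, at 156678532 to 156719086, which was 0.47 (SE 0.13) higher. Pea15a lies close to Fcer1a, which starts at 173221284, and DESeq2 called it (adjusted p = 0.0113). A share over 20 Mb cannot tell whether flanking DNA affects a single close gene, so this stays open for Pea15a.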

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

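The newer version of edgeR's method, the epithelial covariate and the KEGG groups were chosen after seeing the data. Against 0 genes by edgeR, DESeq2 called 127 (86 higher, 41 lower), limma-voom 2 (both lower) and edgeR with no filter on low counts 3 (1 higher, 2 lower). Of the 20 genes the naming rule took, 19 passed DESeq2 and 1 the unfiltered fit, against 0, with no change of sign in 319 values. These genes were picked by small p from the same counts, and each parted the groups. Neither the passes nor the steady signs are therefore evidence of their own. The count was 0 under every other setting, including each fit without 1 library (0 to 0), although genes at an unadjusted p under 0.05 went from 1145 to 4344 without wild type replicate 1 and to 405 without knockout replicate 1. The cause was not tested. Fcer1a kept its direction in all settings (log2 -6.22 to -3.42 without 1 library, -1.27 with the covariate, adjusted p 0.0679 to 0.9998 over all alternatives that gave one).

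Of the 55 lists, 21 passed camera, 16 to 24 without 1 library, 15 with the epithelial covariate (6 of the 21), 0 with an estimated correlation and 0 with fry. The cause was not tested. With 313 KEGG groups in place of the lists, 51 passed and 0 with an estimated correlation. With the covariate the lists that kept the call were interferon gamma, type I interferon, MHC class I, proinflammatory, squamous and reticulum stress genes, and the others of the 21 lost it (neutrophil median -0.02, adjusted p = 0.201, and oxidative phosphorylation 0.04, 0.805). The interferon gamma median was 1.25 to 1.91 without 1 library, and its 1.67 fell short with an estimated correlation (adjusted p = 0.860) and with fry (0.530). Among other settings, 4 lists passed in all of them: interferon gamma, type I interferon, MHC class I and proinflammatory genes. Medians changed sign for goblet genes (-0.00012 without wild type replicate 2, 0.94 without wild type replicate 1, -0.0040 with the covariate), enterocyte markers (-0.088 with no filter), matrix proteases (0.022) and endothelial markers (0.30, both with the covariate). The cause was not tested. Component 1 held 55.2% over 2000 genes and 51.4% over all.

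With the replicate number as a replicate block, a paired fit, 0 genes passed and Fcer1a was at -3.99. The block gave 21 lists but not the same ones, since the enterocyte (adjusted p = 0.0545), antioxidant (0.0618) and proximal (0.0650) lists lost the call, and the goblet median was 0.44. The alternatives written for normalized values were not run, since the tables hold counts. The labels do not say that the numbers pair the mice. Deviations of same-numbered libraries correlated at 0.42, -0.13 and 0.01, and those of the other pairs at -0.48 to 0.39. That gives no clear sign of pairing, but so few libraries cannot exclude it.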

Other observations

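The tests of more T and cytotoxic cells, of summed gene copies, of distance from Fcer1a, of DESeq2 on other splits and of near-absent genes on other splits were chosen after the result was seen, as were the genes named here outside the rule.

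Around Glo1 on chromosome 17, genes that parted the groups went both ways. Cmtr1 was higher in knockout gut, at 55.6, 49.8 and 62.1 CPM in wild type and 75.0, 84.7 and 71.4 CPM in knockout libraries, a log2 fold change of 0.46. Dnah8, a dynein heavy chain gene (30624354 to 30877365), was at 36.6 CPM in wild type and 14.1 CPM in knockout gut, a log2 fold change of -1.38, and the noncoding Gm10503 (30920338 to 30963220) had 143, 195 and 169 counts in wild type and 0, 0 and 1 in knockout libraries. Gm50240 and Gm50244, which lie beside and within Glo1 on the opposite strand, were lower by all 3 libraries, at -1.10 and -1.35. Btbd9, the neighbour on the other side (30215524 to 30576488), was at 44.5, 46.3 and 46.6 CPM in wild type and 45.2, 46.3 and 40.9 CPM in knockout libraries. None of these passed edgeR's test (adjusted p from 0.136 to 0.937). Limma-voom called Gm10503 and Glo1-ps (adjusted p = 0.0230 for each), as did DESeq2 (7.8e-10 and 4.8e-15), while edgeR gave Glo1-ps an adjusted p of 0.145.

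Of 3 genes near absent in 1 group (under 0.1 CPM in all its libraries and at least 1 CPM in all others), Glo1-ps, a processed pseudogene of Glo1 on chromosome 2 (35340409 to 35340963), had 229, 547 and 333 counts in wild type and 0 in each knockout library, at least 413-fold lower against 3 counts over the group. The others were Gm10503 and Tgtp1. Reads moving between near-identical copies stay open: the sums of Glo1 with Glo1-ps and of Tgtp1 with Tgtp2 differed by -1.43 and 2.75 (log2), but Glo1 and Tgtp2 alone already parted the groups, so the sums decide nothing, and Gm10503 had no such test. DNA flanking Fcer1a is argued against, since 0 of the 3 lie within 20 Mb of it. A variant elsewhere that differs between the groups of mice may account for the chromosome 17 genes and stays open. Of 31 other genes within 1 Mb of Glo1, 5 (16.1%) parted the groups, 4 lower and 1 higher, against 13.0% of all tested genes (exact binomial test, one-sided, p = 0.377). That test takes the 31 genes as independent, but Gm50244 and Dnah8 overlap Glo1 and may hold its reads. A share over 1 Mb on each side also cannot tell of a shorter stretch, so this p decides nothing. With 10 splits of the 6 libraries a share under 0.05 cannot be had; 1 split, the real one, gave 3 near-absent genes, and the highest other gave 1.

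For the interferon gamma list, a single library is argued against as the cause, since the median of 1.67 stayed at 1.25 or more without each. A larger share of epithelium is argued against as the whole cause, since with the epithelial markers as a covariate the median was 1.39. A rise of T and cytotoxic cells as large as that of the list is argued against as well. The larger of their 2 list medians was 0.14 (SD of its members 0.667). These medians cannot tell of a smaller rise or of more active cells, so both stay open. Ifng itself had 3 counts in wild type and 37 in knockout libraries. With 10 splits no share under 0.05 can be had: 1 split, the real one, gave a median as large in size, and the highest other gave 1.26. Camera at the preset correlation also called the list on splits that mix the genotypes. Its adjusted p was 4.2e-07 with wild type 1 and 2 and knockout 3 on 1 side. It was 0.00109 with wild type 1 and 3 and knockout 3, and 2.2e-05 with wild type 1 and knockout 1 and 2. A small camera p is thus not particular to the real split. The genotype itself, a difference between lines of mice and a difference in the course of inflammation stay open and were not tested apart.

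Among the clock genes, Cry1 and Per2 were lower and Nr1d1 was higher. For a shift of the whole clock by time of tissue collection, the prediction was set on an index of other clock genes. It asked for all knockout libraries above all wild type ones in Nr1d2, Dbp, Tef, Per3 and Ciart over Arntl, Npas2 and Clock. The groups overlapped instead, with the index at 0.692, 0.15 and 0.907 in wild type and 0.805, 0.838 and 0.624 in knockout libraries. That overlap argues at most against a shift that raises this index far enough to part the groups. A shift in time need not raise the index, so the time of collection stays open. A smaller shift stays open as well, since the wild type values alone spread widely and the index leaves out Cry1, Per2 and Nr1d1. Whether epithelial content matters cannot be told apart, because the index did not part the groups to begin with (a difference of 0.173, and 0.148 with the covariate).

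The counts of calls were set against other splits of the 6 libraries, where 10 splits allow no share under 0.05. By edgeR, 10 of 10 splits gave 0 genes, the highest other included (0). Camera called 21 lists on the real split and up to 28 on another, with 6 of 10 splits at 21 or more. DESeq2 called 127 genes on the real split and up to 1106 on another, with 3 of 10 splits as high. The splits with 1091 and 1106 genes set wild type library 1 and knockout library 1 with knockout library 2 or 3 against the rest, which points to a structure of the samples other than genotype.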
